A study of Mus musculus with 10 samples.

How the data were processed

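Total RNA of 10 mouse neuroblastomas, 5 per genotype, was labelled with Cy3 and hybridised against a Cy5-labelled reference RNA on Agilent SurePrint G3 mouse arrays, per the labels' protocols; all arrays had the same dye orientation. Per the labels each array is 1 tumour of a different mouse. Spot intensities were extracted with Agilent Feature Extraction 10.7.3.1, per the file headers, with probe positions on build mm9. Each array held 62976 spots, of which 59305 were spots of 55681 distinct probes and 3671 were controls. The scanner's own log10 ratios of processed Cy5 over Cy3, deposited with the intensities per the file headers, were not used for tests. The deposited value table holds log2 ratios, found by comparison to be log2 of the scanner-processed Cy3 over Cy5 intensity within 5.01e-04 on every array, which leaves scale, centring and direction known; its medians lay between -0.185 and -0.034. What the authors did with these values afterwards is not given in the sources used here.

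From the deposited intensities, the mean signal of each spot was corrected for the median local background with normexp (offset 50), and log2 ratios were normalised within each array by loess with control spots at weight 0. Ratios were turned to tumour over reference. No scaling between arrays was done. Spots marked as non-uniform or population outliers in either channel, 177 to 345 per array, were set to missing, and no spot was saturated. Spots of a probe were averaged. Probes were kept when well above background in Cy3 on at least 5 of the 10 arrays, which left 30857 probes, and each gene was represented by its probe of highest mean intensity, which gave 22263 genes; 22181 of them had a value on every array. Of the gene names, 14163 were matched by accession, 840 by symbol and 179 by synonym to RefSeq names of assembly GRCm38.p6, used for names only, and 7081 kept the name of the array. Among 5831 genes with more than 1 kept probe, 65 had probes that passed in both directions.

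Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated test, two-sided) with Benjamini-Hochberg adjustment over genes at 0.05. Gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01 over the 26 lists with at least 4 measured members, and again with an estimated correlation, with fry and with an exact permutation of tumour means (genes with a value on every array) over the 252 assignments of the tumours, whose smallest two-sided p is 0.00794. Lists of sex-linked genes and of genes known to vary between these mouse strains were used as checks and not tested as lists. Where a probe was well above background on no array of a group, its fold is a bound, from Cy3 values scaled by Aquantile after loess, and is open to dye bias since dyes were not swapped. The genes named are taken from the 12 largest rises and 12 largest falls among called genes with a symbol other than a clone, predicted gene or accession, Alk and Mycn, and up to 4 members of each list with the smallest p, or up to 8 where more passed. Which of these list members are printed was chosen after their values were seen, and they need not be those with the smallest p. Other genes are said to have been chosen after their values were seen.

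The procedure was tested on simulated data with 5 arrays per group, in which 200 of 22263 genes were changed. It recovered 47.8% of genes changed by 0.5, 89.6% of those changed by 1 and 98.5% of those changed by 2 on the log2 scale. There were 10 false calls among 167. The simulated noise was independent between genes and few genes were changed, whereas 26.5% of genes were called in the data. These figures need not hold there. Arrays of a group correlated at 0.915 to 0.972 in ALK/MYCN and 0.867 to 0.937 in MYCN tumours, and at 0.805 to 0.910 between groups; no array repeated another. The first principal component held 43.8% and the next 17.1% of the variance.

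Slides were read from the files and taken as batches. Slide 1 held 1 tumour of each group, slide 2 held 3 ALK/MYCN and 1 MYCN, and slide 3 held 1 ALK/MYCN and 3 MYCN. Alternatives listed before the data were examined were other background corrections, normalisations, filters, probe summaries, variance models, blocks and the removal of each tumour. Centring on spike-in spots, removal of 3 tumours with markers of other tissues, and a covariate for stromal content were added after seeing the data, as were 37 gene families defined by symbol.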

Results

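Gene expression was measured in neuroblastomas of 10 transgenic mice. In 5 of them the tumour arose in animals carrying both a MYCN transgene and the F1174L mutant of the receptor tyrosine kinase ALK (ALK/MYCN), and in the other 5 in animals carrying the MYCN transgene alone (MYCN). Each tumour RNA, labelled with Cy3, was hybridised to one Agilent mouse array together with a Cy5-labelled reference RNA pooled from 11 mouse cell lines, so that every value is a log2 ratio of tumour over reference. Between 53.8% and 58.7% of the probe spots were well above background in the tumour channel, and this share did not differ between the groups (56.8 ± 1.96% in ALK/MYCN and 56.5 ± 1.10% in MYCN tumours, SD, n = 5 each, exact permutation p = 0.762, two-sided). The number of arrays limits the precision. The ALK/MYCN mice were on a C57BL/6 x 129X1/SvJ background and the MYCN mice on 129X1/SvJ, so that genotype and background cannot be told apart in any difference given here.

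The comparison asks which transcripts differ between tumours with and without mutant ALK when MYCN is present in both. ALK/MYCN tumours expressed sets of neuronal and peptidergic genes, and a part of the MAPK-responsive genes, at higher levels. Markers of endothelium and macrophages were lower on average, with overlap between the groups. MYC target and cell cycle genes were lower relative to the other genes of the array. These are shifts of lists that passed camera with a preset correlation. With an estimated one 0 of the 26 lists passed, and the endothelial and macrophage lists also missed an exact permutation (adjusted p = 0.0516 each). Of 22263 genes tested, 5892 (26.5%) differed at an adjusted p of 0.05 by limma with Benjamini-Hochberg adjustment, 3169 of them higher and 2723 lower in ALK/MYCN tumours. The groups did not overlap in any of the 12 largest rises and in 8 of the 12 largest falls. Since these genes were picked for their differences, this is no separate support: 4119 of all 5892 called genes had no overlap. The difference exceeded 1 on the log2 scale in 499 of the higher genes and lay under -1 in 483 of the lower ones. Over the array, the groups did not overlap in 19.9% of the tested genes, where chance would give 0.794%. The arrays lay on 3 slides that each held both groups, and with slide as a block 4352 genes passed. Of the 5889 called genes measured on every slide, 5784 had the same sign within each of the 3. That agreement is fixed in advance for the 4119 called genes without overlap of the groups. The count therefore does not test whether the differences hold across slides. Without ALK/MYCN 5 the number of lower genes was 1771. The balance of directions depended on scaling. With median centring 4454 genes were higher and 1349 lower, and with spike-in centring 8816 and 834.

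The probe for Alk (chromosome 17, 72218357 to 72218416, build mm9) gave 4.35 ± 0.48 in ALK/MYCN and 4.28 ± 0.04 in MYCN tumours (SD, n = 5 each), a difference of 0.07 ± 0.20 (SE, limma adjusted p = 0.837). The probe for Mycn (chromosome 12, 12943193 to 12943252, mm9) gave 3.65 ± 0.77 and 0.80 ± 0.43, a rise of 2.85 ± 0.35 (limma adjusted p = 7.62e-04) with no overlap between the groups. Both probes were designed on mouse sequence. Whether they hybridise with transcripts of the transgenes was not determined, so these values check neither the ALK nor the MYCN label.

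**Figure D1:**
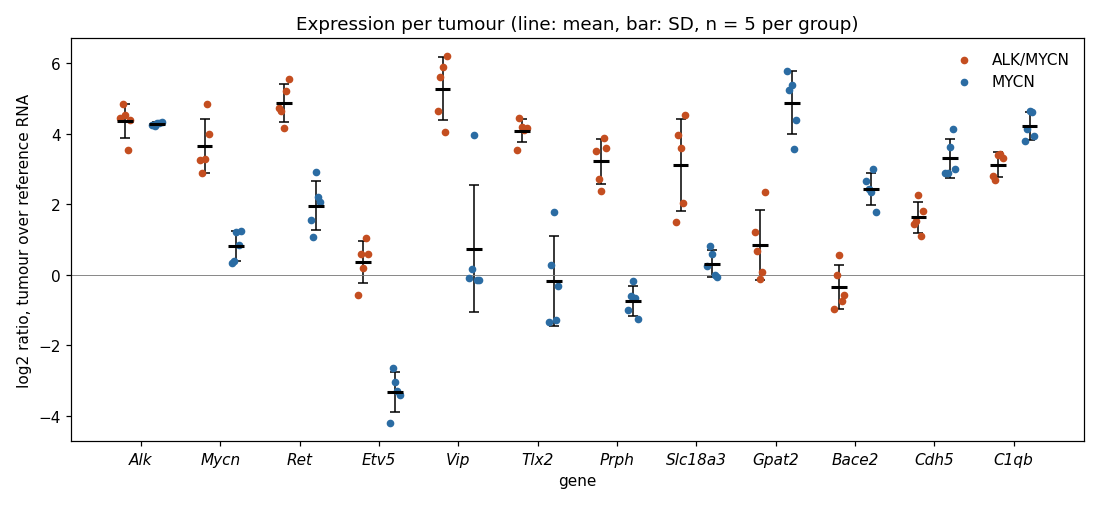
Log2 ratio of tumour over reference RNA (vertical axis) for 12 genes (horizontal axis) in each ALK/MYCN and MYCN tumour, with points for tumours, lines for group means and bars for SD, n = 5 per group. Alk lies at 4.35 and 4.28 in the 2 groups, whereas Etv5 lies at 0.36 and -3.32; MYCN 3 stands apart from the other MYCN tumours in Vip at 3.96.

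The largest rises included several genes of peripheral neurons. Vip, encoding the vasoactive intestinal peptide, rose by 4.54 ± 0.80 (SE, limma adjusted p = 0.00365), although MYCN 3, at 3.96, was close to the ALK/MYCN tumours while the other MYCN tumours lay between -0.16 and 0.15, and its probe was well above background on 1 of the 5 MYCN arrays. Tlx2, a homeobox gene of the enteric and autonomic lineage, rose by 4.27 ± 0.53, and Prph, encoding the intermediate filament peripherin, by 3.96 ± 0.30. Ret, the receptor tyrosine kinase for ligands of the GDNF family, rose by 2.90 ± 0.35 and the ETS transcription factor gene Etv5 by 3.68 ± 0.33 (limma adjusted p = 7.06e-04 and 2.56e-04). Egln3, encoding a prolyl hydroxylase, rose by 3.70 ± 0.79, Pgm5 by 3.71 ± 0.59, Ptchd1 by 3.05 ± 0.51 and Trnp1 by 3.05 ± 0.43. Of the 5 MYCN arrays, 4 measured Tlx2 above background, 3 measured Prph and Ptchd1, and 2 measured BRN1-A, so the sizes of these rises are uncertain. With Cy3 alone, that is without reference and loess, they were 7.64 for Vip, 6.41 for Tlx2, 7.20 for Prph, 4.76 for Ptchd1 and 5.94 for BRN1-A. Pgm5 rose by 2.32 as the mean over its probes. Edil3, which encodes a secreted integrin ligand, was not well above background on any MYCN array and was at least 6.14-fold higher in ALK/MYCN tumours (limma adjusted p = 9.99e-04). The transcript named BRN1-A by the array, described there as a long intergenic RNA, rose by 3.39 ± 0.82 (limma adjusted p = 0.0141) but did not pass in the scanner-processed signals (adjusted p = 0.0604) or without ALK/MYCN 3, MYCN 2 and MYCN 5 together (adjusted p = 0.0647).

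Among the largest falls were genes of several other cell types. Fabp4, a fatty acid binding protein of adipocytes, endothelium and macrophages, fell by 4.31 ± 1.20 (SE, limma adjusted p = 0.0252). Its call was lost without ALK/MYCN 1, ALK/MYCN 2, ALK/MYCN 5 or MYCN 4, with limma adjusted p between 0.0538 and 0.0624. The chemokine gene Ccl6 fell by 2.97 ± 0.49, Ly6c1, a surface antigen of endothelium and myeloid cells, by 2.86 ± 0.68, and the macrophage scavenger receptor gene Marco by 2.70 ± 0.80. Marco lost its call without ALK/MYCN 1, 2, 4 or 5 or MYCN 2, with limma adjusted p between 0.0536 and 0.0720. With the stromal covariate (the mean of the fibroblast, endothelial and macrophage lists) Ccl6 fell by 1.61, while Fabp4, Ly6c1, Marco and Meis2, at -2.31, -1.25, -0.83 and -1.82, did not pass (limma adjusted p = 0.289, 0.166, 0.437 and 0.212). Gpat2, encoding a mitochondrial acyltransferase, fell by 4.03 ± 0.53 and the aspartyl protease gene Bace2 by 2.79 ± 0.31 (limma adjusted p = 9.86e-04 and 5.12e-04). The transcription factor genes Dach1 and Meis2 fell by 2.91 ± 0.50 and 2.80 ± 0.74. Asb4 fell by 2.62 ± 0.46 and the skeletal muscle myosin gene Myh8 by 2.61 ± 0.57. With Cy3 alone these were -4.51 and -5.53, and Asb4 was at -1.48 as the mean over its probes. Muscle markers stood out in MYCN 2 and MYCN 1. The signal of the beta globin probe Beta-s was lower by 2.75 ± 0.39 (limma adjusted p = 0.00137; 1.30 in the scanner-processed signals), but closely similar globin genes can share it, and an allele difference between the mouse backgrounds was not tested. The immunoglobulin probe Igh-VJ558 fell by 4.16 ± 0.81, but it belongs to a multigene family and another probe of that name passed in the opposite direction, so its direction is uncertain. It was well above background on 2 and Asb4 on 4 of the 5 ALK/MYCN arrays.

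Genes that respond to MAPK signalling rose in part. Of 22 measured members of the MAPK feedback and ETV list, 7 rose and none fell (8 higher and 1 lower adjusted over the list alone, 12 and none with spike-in centring). The other 15 did not pass, and the differences of the members ran from -1.44 to 3.68. Etv5 and Ret were joined by Etv4 at 1.65 ± 0.22, the secreted neuropeptide precursor gene Vgf at 0.64 ± 0.12 and the Ras pathway inhibitor genes Spred2 at 0.60 ± 0.07 and Spred3, which was not well above background on any MYCN array and was at least 1.39-fold higher. The list passed camera from limma (adjusted p = 0.00831) and an exact permutation of tumour means (adjusted p = 0.0459), but not camera with an estimated correlation (adjusted p = 0.477 with an estimated correlation). Its mean difference was 0.87, 0.17 and 0.76 on slides 1, 2 and 3. Of 12 immediate early genes, 2 rose, 1 of them adjusted over the list alone, against 7 with spike-in centring and 4 with median centring. Klf6 rose by 1.12 ± 0.22, while Nr4a1, at 2.50 ± 0.83, lost its call on removal of any tumour but ALK/MYCN 4 (limma adjusted p between 0.0657 and 0.102), and with slide as a block (adjusted p = 0.102). That list passed camera at an adjusted p of 0.0369 in limma, with adjusted p = 0.547 with an estimated correlation. It did not pass without ALK/MYCN 2, ALK/MYCN 3, MYCN 1, MYCN 4 or MYCN 5 (adjusted p between 0.0518 and 0.160), in the scanner-processed signals (adjusted p = 0.0519), with Cy3 alone (adjusted p = 0.0588) or in the exact permutation (adjusted p = 0.0952). Slide differences were 1.43, 0.59 and 0.75.

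Of the 26 lists, the neuronal list held the most genes that rose. Of 27 genes of neuronal differentiation, 18 rose and 1 fell (21 and 2 adjusted over the list alone). These counts were 11 and none in the scanner-processed signals and with the stromal covariate and 12 and 3 after scaling of the arrays. The cell adhesion gene Cntn1 rose by 1.64 ± 0.09, the tau gene Mapt by 2.40 ± 0.29 and the RNA-binding protein gene Elavl2 by 1.34 ± 0.15. Of 13 cholinergic and peptidergic genes, 8 rose and 1 fell, with the same numbers adjusted over the list alone. Besides Vip and Tlx2 these included the vesicular acetylcholine transporter gene Slc18a3 at 2.81 ± 0.54, the galanin gene Gal at 2.52 ± 0.43 and the acetylcholinesterase gene Ache at 1.60 ± 0.22; Nts fell by 0.58 ± 0.18 and lost its call on removal of 7 of the 10 tumours in turn (limma adjusted p between 0.0567 and 0.0858) and with slide as a block (adjusted p = 0.110). Of 26 genes of noradrenergic identity, 11 rose and none fell (12 and none adjusted over the list alone), against 5 and 3 after scaling of the arrays. They were 6 and none in the scanner-processed signals, and 7 and none with slide as a block and without ALK/MYCN 5. The 11 include Mycn at 2.85, whose probe was not shown to miss the transgene. They also include Ret at 2.90, which counts in the MAPK list as well. Slc18a2, the vesicular monoamine transporter gene, rose by 1.50 ± 0.14, while Th, encoding tyrosine hydroxylase, differed by 0.23 ± 0.06 (limma adjusted p = 0.0140), with its sign turned at -0.019 after median centring and at -0.040 after scaling of the arrays, and did not pass with slide as a block (adjusted p = 0.0537). The median of the noradrenergic list, 0.21, turned to -0.034 after that scaling and was 0.047 in the scanner-processed signals. It was 0.46 with spike-in centring and 0.70 with Cy3 alone. The median of the cholinergic list, 1.60, was 3.43 with Cy3 alone, where the differences of Slc18a3 and Ache moved by over 1.5 times.

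The neuronal, cholinergic and noradrenergic lists passed camera from limma (adjusted p = 2.68e-07, 0.0143 and 0.00831) and the exact permutation of tumour means (adjusted p = 0.0258 for each), and none passed camera with an estimated correlation (adjusted p = 0.477 with an estimated correlation for each). Within slides 1, 2 and 3 the mean difference of the neuronal list was 0.82, 0.82 and 0.87, that of the cholinergic list 2.17, 1.41 and 1.76 and that of the noradrenergic list 0.47, 0.60 and 0.57. In the scanner-processed signals the noradrenergic list did not pass (adjusted p = 0.155) and the cholinergic list narrowly missed (adjusted p = 0.0503). The latter also missed with median centring (adjusted p = 0.0502) and when probes had to be above background on all arrays (adjusted p = 0.890) or in both channels (adjusted p = 0.0618).

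MYC target genes and cell cycle genes were lower in ALK/MYCN tumours relative to the other genes of the array. Of 30 MYC targets, 20 fell and 1 rose, also adjusted over the list alone. Ppan, a ribosome biogenesis factor gene, fell by 0.84 ± 0.11, Odc1, encoding the rate-limiting enzyme of polyamine synthesis, by 0.63 ± 0.09, and the nucleolar protein genes Npm1 and Fbl by 0.51 ± 0.06 and 0.49 ± 0.06. Of 28 cell cycle genes, 16 fell and 1 rose (19 and 1 adjusted over the list alone), among them the mitotic kinase gene Plk1 by 0.68 ± 0.10 and Mybl2 by 0.75 ± 0.09. Both lists passed camera from limma (adjusted p = 3.54e-08 each) and the exact permutation (adjusted p = 0.0258 each), and neither passed with an estimated correlation (adjusted p = 0.477 with an estimated correlation). That estimate was 0.45 for each list, far above the preset 0.01. Mean differences within slides 1, 2 and 3 were -0.50, -0.27 and -0.45 for MYC targets and -0.47, -0.24 and -0.29 for the cell cycle list. Centring the arrays on spike-in control spots, chosen after seeing the data, moved the median of all genes to 0.25 and left 8 of the MYC targets lower and 3 higher and 5 of the cell cycle genes lower and 2 higher; Fbl was not among them (adjusted p = 0.0515). Median centring left 12 MYC targets and 8 cell cycle genes lower.

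Metabolic and stress lists moved less uniformly. Of 21 genes of the mTORC1, sterol and serine list, 6 rose and 2 fell (8 and 2 adjusted over the list alone). With spike-in centring 12 rose and 1 fell, and with the stromal covariate the list median was 0.58 against 0.16. The members that rose most clearly belong to sterol synthesis, with Hmgcs1 at 1.44 ± 0.26 and Idi1 at 1.22 ± 0.18, whereas Shmt2, of serine and glycine metabolism, fell by 1.77 ± 0.24. The list passed camera (limma adjusted p = 0.0280), with adjusted p = 0.547 with an estimated correlation. It missed with median centring (adjusted p = 0.0841), in the exact permutation (adjusted p = 0.138), with slide as a block (adjusted p = 0.0677), without MYCN 1 (adjusted p = 0.0614) and without MYCN 3 (adjusted p = 0.0507). Its mean difference was 0.32, 0.037 and 0.20 on slides 1, 2 and 3. Of 18 FOXO targets, 5 rose (3 without ALK/MYCN 4, ALK/MYCN 5, MYCN 1 or MYCN 4) and none fell (1 without ALK/MYCN 3 or MYCN 1), also adjusted over the list alone, including Cited2 at 1.36 ± 0.11 and the insulin receptor substrate gene Irs2 at 1.06 ± 0.16, but the list did not pass (limma adjusted p = 0.141). The JAK/STAT list (3 of 11 lower), the p53 list (3 of 17 lower), the hypoxia list (3 of 19 higher and 1 lower) and the ribosomal protein list (7 of 22 lower, but 1 lower and 10 higher with spike-in centring), each with the same counts adjusted over the list alone, did not pass either (limma adjusted p = 0.211, 0.211, 0.395 and 0.0846). With spike-in centring the JAK/STAT list had 2 genes higher and 2 lower, the p53 list 1 and 2, and the hypoxia list 6 and none. The FOXO list then had 10 higher and none lower, with a median of 0.31 against 0.058. With the stromal covariate the JAK/STAT list had 1 higher and none lower, and its median turned from -0.29 to 0.47. The median of the ribosomal list, -0.043, turned to 0.033 in the scanner-processed signals and 0.21 with spike-in centring, and that of the p53 list, -0.067, to 0.015 with median centring and 0.19 with spike-in centring. Members of these lists that passed included Tnfrsf10b, a death receptor gene, which fell by 1.17 ± 0.14, and the cytokine receptor gene Osmr, which fell by 1.36 ± 0.37 and lost its call without ALK/MYCN 1 or ALK/MYCN 4 (limma adjusted p = 0.0516 and 0.0560).

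**Figure D2:**
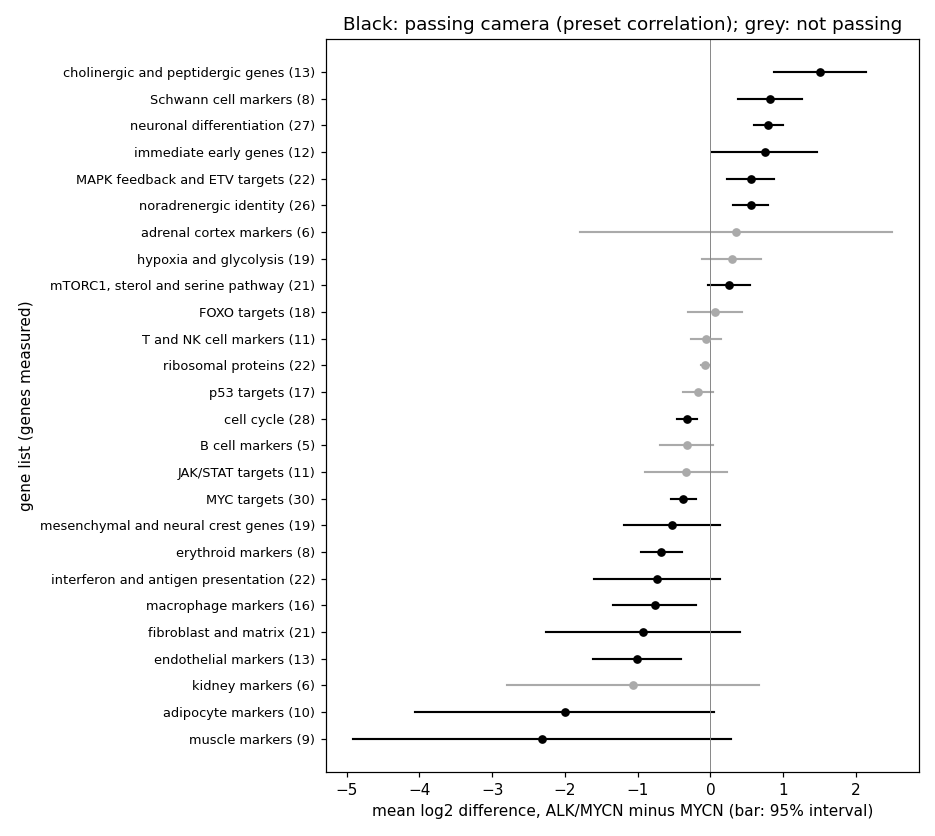
Mean log2 difference between ALK/MYCN and MYCN tumours (horizontal axis) for each of 26 gene lists (vertical axis, with the number of genes measured), with points for differences of tumour means, bars for 95% intervals over 5 tumours per group, and black for lists that passed camera with the preset correlation of 0.01. The neuronal list lies at 0.79 and the endothelial list at -1.01, and no list passed with an estimated correlation (lowest adjusted p = 0.477).

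Markers of endothelium and macrophages were lower on average in ALK/MYCN tumours, but the groups overlapped. The endothelial list mean, centred per gene, was 0.016 in MYCN 1 and 0.057 in MYCN 5, against 0.12 in ALK/MYCN 3. The macrophage list mean was -0.32 in MYCN 1, within the ALK/MYCN range of -0.68 to -0.13, and 0.018 in MYCN 5. In MYCN 2, MYCN 3 and MYCN 4 the means were 0.59 to 1.03 for endothelium and 0.65 to 0.84 for macrophages. Of 13 endothelial genes 10 fell and none rose, also adjusted over the list alone, with the claudin gene Cldn5 falling by 2.17 ± 0.43 and the VE-cadherin gene Cdh5 by 1.68 ± 0.28. Of 16 macrophage genes 12 fell and none rose (13 and none adjusted over the list alone), including the receptor gene Csf1r by 1.35 ± 0.35, the complement gene C1qb by 1.09 ± 0.21 and the adaptor gene Tyrobp by 1.03 ± 0.25. The median difference of the macrophage list was -0.91, and the members with the smallest p include smaller falls than these. These lists passed camera from limma (adjusted p = 2.63e-05 and 8.19e-06), with adjusted p = 0.477 with an estimated correlation for each, and the exact permutation of tumour means gave adjusted p = 0.0516 for each. On slides 1, 2 and 3 the endothelial difference was -0.52, -1.52 and -1.03 and the macrophage difference -0.24, -1.14 and -0.64. With the stromal covariate, which holds both of these lists, 1 endothelial and 1 macrophage gene stayed lower. Cldn5, C1qb and Tyrobp did not pass (limma adjusted p = 0.0570, 0.0567 and 0.208). Spike-in centring left 6 macrophage genes lower. The difference of Csf1r moved by over 1.5 times with the mean over its probes.

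Fibroblast and matrix genes were less uniform. Of 21 measured 5 fell and none rose (4 and none adjusted over the list alone; 2 to 10 on leaving out each tumour, 10 without MYCN 1, 2 with slide as a block, and 5 higher and none lower with the stromal covariate). The matrix gene Fbln2 fell by 1.60 ± 0.30 and the smooth muscle actin gene Acta2 by 1.03 ± 0.24. The difference was 0.63 on slide 1, where MYCN 1 was the only MYCN tumour, and -2.31 and -0.64 on slides 2 and 3. Of 19 mesenchymal and neural crest genes 4 fell and none rose (2 and none adjusted over the list alone, 1 and 1 with spike-in centring or the stromal covariate, 3 and 1 with median centring), among them Notch3 by 1.68 ± 0.27, and the slide differences were 0.22, -1.17 and -0.45. Both lists passed camera (limma adjusted p = 0.00831 and 0.0153), with adjusted p = 0.547 with an estimated correlation for each, and neither passed the exact permutation (adjusted p = 0.178 and 0.152). Both turned to higher with the stromal covariate (adjusted p = 0.0510 and 0.543), which itself holds the fibroblast list. Of 8 Schwann cell markers 4 rose and none fell, also adjusted over the list alone, with Fabp7 rising by 2.71 ± 0.36 and the transcription factor gene Foxd3 by 1.67 ± 0.20. That list passed camera (limma adjusted p = 0.0189) and the exact permutation (adjusted p = 0.0258), with adjusted p = 0.547 with an estimated correlation, and missed in the scanner-processed signals (adjusted p = 0.0907). It also missed when probes had to be above background on all arrays (adjusted p = 0.274) or in both channels (adjusted p = 0.0679), and without ALK/MYCN 3, MYCN 2 and MYCN 5 (adjusted p = 0.133). Its slide differences were 0.92, 0.65 and 1.16.

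Blood and immune lists differed in part. Of 8 erythroid markers 6 fell and 1 rose (6 and 2 adjusted over the list alone), with Alas2, the erythroid enzyme of haem synthesis, falling by 2.56 ± 0.34 and the alpha globin gene Hba-a1 by 0.79 ± 0.14; Alas2 did not pass in the scanner-processed signals (limma adjusted p = 0.0672), nor Hba-a1 after median centring (limma adjusted p = 0.401). With Cy3 alone Hba-a1 differed by -3.70, and the median of the list was -3.62 against -0.59. The erythroid list passed camera (limma adjusted p = 0.0153), with adjusted p = 0.477 with an estimated correlation, and missed in the scanner-processed signals (adjusted p = 0.145) and after median centring (adjusted p = 0.227), with 2 genes lower in each. It also missed when probes had to be above background in both channels (adjusted p = 0.128) or without ALK/MYCN 3, MYCN 2 and MYCN 5 (adjusted p = 0.0590). On slides 1, 2 and 3 it differed by -0.31, -0.76 and -0.72. None of 22 interferon and antigen presentation genes passed on its own, over all genes or adjusted over the list alone, the smallest p belonging to B2m at -1.25 ± 0.47 (limma adjusted p = 0.0719). The list nevertheless passed camera (limma adjusted p = 0.00407), with adjusted p = 0.547 with an estimated correlation and an exact permutation adjusted p of 0.138, and its slide differences were 0.18, -1.53 and -0.82. With the stromal covariate its median turned from -0.62 to 0.14, with 2 genes higher. None of 11 T and NK cell markers passed, and 1 of 5 B cell markers fell, likewise adjusted over the list alone (limma camera adjusted p = 0.652 and 0.375). With spike-in centring 3 T and NK cell markers were higher, and with median centring 2, where the list median turned from -0.043 to 0.21 and 0.10. The B cell list had 1 gene higher and 1 lower with spike-in centring, where its median turned from -0.22 to 0.035. The B cell gene was Cd79b at -1.26 ± 0.36, which lost its call without ALK/MYCN 1, ALK/MYCN 2, ALK/MYCN 5 or MYCN 4 (limma adjusted p between 0.0596 and 0.0620), with slide as a block (adjusted p = 0.0507) and after scaling of the arrays (adjusted p = 0.0921).

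Single tumours carried markers of neighbouring tissues. The adrenal cortex list averaged 3.79 above the gene means in ALK/MYCN 3, the kidney list 3.46 in MYCN 5, the adipocyte list 2.94 in MYCN 4, and the muscle list 5.15 in MYCN 2 and 2.17 in MYCN 1. None of 6 adrenal cortex and none of 6 kidney genes passed, over all genes or adjusted over the list alone (limma camera adjusted p = 0.652 and 0.244). Of 9 muscle genes 1 fell (3 in the scanner-processed signals and with Cy3 alone), the myosin gene Myh4 by 2.60 ± 0.54, while Myh1, not well above background on any ALK/MYCN array, did not pass (limma adjusted p = 0.0544) except without MYCN 2 or MYCN 4 (limma adjusted p = 0.0158 and 0.0316) and under some other settings. Of 10 adipocyte genes 3 fell (none with the stromal covariate); both counts were the same adjusted over the list alone. The muscle and adipocyte lists passed camera (limma adjusted p = 0.00834 and 0.00831), with adjusted p = 0.547 with an estimated correlation for each, and exact permutation adjusted p of 0.0258 and 0.103. Slide differences were -3.22, -0.77 and -2.59 for the muscle list and -1.36, -3.39 and -2.74 for the adipocyte list. Without ALK/MYCN 3, MYCN 2 and MYCN 5, an alternative chosen after seeing the data, 3685 genes passed. Of these 12 neuronal genes were higher, and 12 MYC targets, 10 endothelial genes and 7 macrophage genes were lower. MYCN 4 and MYCN 1, with the adipocyte and muscle markers given above, were kept in that alternative. The level of Xist, the X inactivation RNA, lay above the midpoint of its range in 3 tumours of each group. With slide as a block, 16 of the 17 lists that passed camera still passed, the mTORC1, sterol and serine list being the exception.

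**Figure D3:**
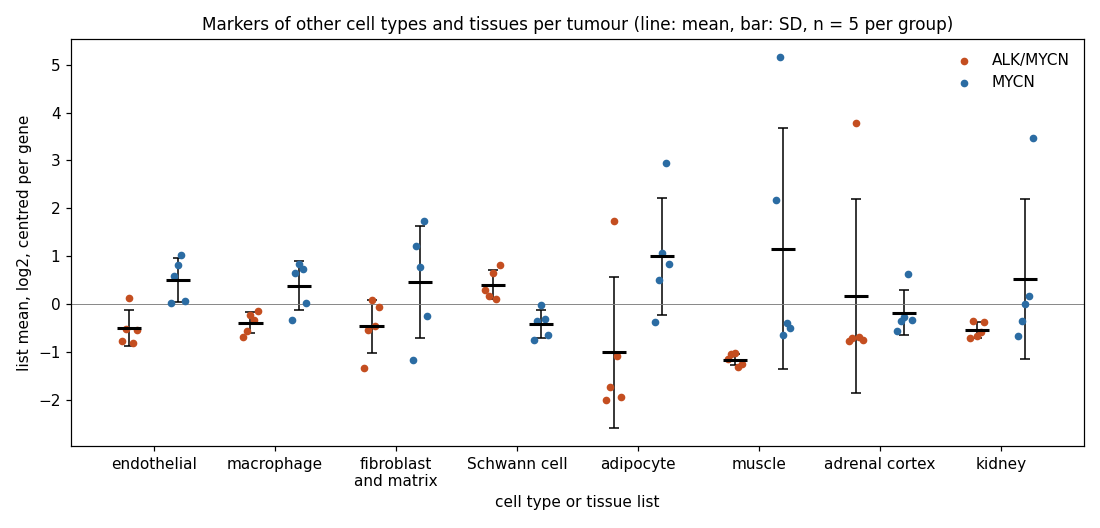
Mean of each marker list per tumour on the log2 scale, centred per gene (vertical axis), for 8 cell types and tissues (horizontal axis), with points for tumours, lines for group means and bars for SD, n = 5 per group. Adrenal cortex markers stand out in ALK/MYCN 3 at 3.79, kidney markers in MYCN 5 at 3.46 and muscle markers in MYCN 2 at 5.15.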

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

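The tests of genetic background, of a smaller and a larger stromal share, of array centring and of a copy gain were chosen after the differences of the lists were seen; those of other splits and of slide were planned. The number of called genes, 5892, was set against other splits of the tumours into 5 and 5. Of 100 drawn splits 1, the real one, gave as many, and the highest of the others gave 285. This argues against chance but does not exclude it, since 1 in 100 is the smallest share the draw can give. The other splits mix the genotypes, so their counts do not show what groups without any difference would give. With slide as a block 4352 genes passed, which argues against slide as the whole cause. Genetic background stays open and cannot be told apart from genotype, since each group has its own background. Of 6 measured genes known to vary between these mouse strains 1 passed, against 26.5% of all tested genes. This count does not bear on background either way. The gene was Wdfy1 at 0.49 ± 0.08 (SE, limma adjusted p = 0.00283, 5 tumours per group). Its call was lost with the mean over its probes at an adjusted p of 0.773.

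The rise of neuronal and cholinergic genes was set against a smaller share of stromal cells in the ALK/MYCN pieces. With the mean of the fibroblast, endothelial and macrophage lists as a covariate the difference of the neuronal list was 0.81 (95% interval 0.52 to 1.10), against 0.79 without it (0.60 to 0.99), which argues against that explanation for the neuronal list. The cholinergic list gave 1.81 (0.96 to 2.66) with it and 1.50 without it. An effect of mutant ALK on the tumour cells and an effect of background remain open, the latter untested.

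The fall of macrophage and endothelial markers was set against a smaller share of all stromal cells. With the fibroblast list as a covariate the macrophage difference was -0.40 (95% interval -0.68 to -0.12) against -0.77 without, and the endothelial difference -0.66 (-1.09 to -0.23) against -1.01 without. Both intervals exclude 0 but reach far toward it, so a general loss of stroma may account for a large part of the fall and cannot be told apart from a fall of these cell types alone. Schwann cell markers moved the other way, but tumour cells could express them too.

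The fall of MYC target and cell cycle genes beside the rise of the Mycn probe was set against 3 explanations. A larger stromal share is argued against by the mean of the 3 stromal lists, which was lower in ALK/MYCN tumours by -0.90 (95% interval -1.70 to -0.10). A gain that spans Mycn and Ddx1, its neighbour on the array, is argued against for the Mycn rise. The upper 95% bound of the Ddx1 difference, a gene chosen after its values were seen, was -0.017, although the sign of Ddx1 turned with spike-in centring. Probes of Nbas, on the same chromosome, were at 0.16 ± 0.17 and 0.37 ± 0.18 (SE, limma adjusted p over probes = 0.523 and 0.169). Copy number itself was not measured. A gain of Mycn alone and signal from the transgene stay open. Centring could account for the fall: with arrays centred on spike-ins the median differences were -0.13 and -0.10, and the intervals of the list means, -0.36 to 0.12 and -0.22 to 0.08, hold 0. At most a fall relative to other genes is therefore shown, and neither list passed camera with an estimated correlation (adjusted p = 0.477 each).

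Spike-in control spots, used in the report only to centre arrays in an alternative, differed between the groups relative to the gene probes. The ratios were taken after the loess fit, in which control spots had weight 0. A shift of the gene probes or of the spike-in spots would therefore give the same difference, and these values do not tell which moved. The mean normalised log2 ratio of the spike-in spots, Cy3 over Cy5, was -0.59 ± 0.07 in ALK/MYCN and -0.33 ± 0.10 in MYCN tumours (SD, n = 5 each). The difference was -0.25 with no overlap (exact permutation p = 0.00794, the smallest possible), and -0.19, -0.25 and -0.27 on slides 1, 2 and 3.

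By chance a single tumour would stand far from the rest of its group in about 1 in 20 combinations. Some of the named genes were chosen after their values were seen. Such tumours were found in 6 of 160 combinations of a named gene and a group, which does not exceed that share. They were found in 7 of 56 combinations of a list and a group. Among genes these were Vip in MYCN 3 at 3.96 (others -0.16 to 0.15), Gal in MYCN 3 at 0.96 (0.42 to 0.56), Ly6c1 in ALK/MYCN 3 at -2.50 (-5.23 to -4.62), Shmt2 in ALK/MYCN 1 at -2.47 (-3.34 to -3.23), Star, a gene of steroid synthesis, in ALK/MYCN 3 at 7.39 (-0.05 to 0.11), and the kidney transporter gene Slc22a6 in MYCN 5 at 4.42 (0.01 to 0.31). Among lists they were the adrenal cortex list in ALK/MYCN 3 at 3.79 and in MYCN 4 at 0.63, the kidney list in MYCN 5 at 3.46, the adipocyte list in ALK/MYCN 3 at 1.74, the FOXO list in ALK/MYCN 3 at 0.39, the MYC target list in MYCN 1 at 0.38 and the erythroid list in MYCN 1 at -0.077.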

How the results depend on the processing

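The spike-in centring, the removal of 3 tumours with markers of other tissues and the stromal covariate were chosen after seeing the data. Under the other alternatives the number of called genes lay between 4129 (without ALK/MYCN 5) and 6430 (array weights), with 7684 probes of 6375 gene names called when every probe stood on its own, and it was 3685 without the 3 tumours, 3346 with the stromal covariate and 9650 with spike-in centring. Leaving out each tumour gave 4129 to 5431 genes, 2358 to 2948 higher and 1771 to 2597 lower. Lower genes numbered 1349 with median centring, 834 with spike-in centring, 1536 without the 3 tumours and 1399 with the stromal covariate; higher genes numbered 8816 with spike-in centring and 1947 with the stromal covariate. The share of calls that were higher, 53.8%, became 76.8% with median centring and 91.4% with spike-in centring, which moved the median of all genes to 0.09 and 0.25; the other background corrections and scalings kept it between 52.4% and 58.9%. The deposited values called 4821 genes, 4479 of them called in the same direction in the main setting. The tumour numbers do not pair the samples, since deviations of same-numbered tumours correlated at -0.09 to 0.34, and across other pairs from -0.50 to 0.52; with the replicate number as a block 4616 genes passed. The cause of the changes was not tested.

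Of 26 lists, 17 passed camera in the main setting and 0 with an estimated correlation (adjusted p = 0.477 or 0.547 for all of the 17, 0.477 to 0.851 over all). The estimates ran from 0.091 for the p53 list to 0.93 for the adrenal cortex list, all above the preset 0.01. The other changes were as follows, as adjusted p. In the scanner-processed signals immediate early genes reached 0.0519, noradrenergic 0.155, cholinergic 0.0503, Schwann 0.0907 and erythroid 0.145; in the deposited values immediate early 0.0516, noradrenergic 0.146, Schwann 0.0903 and erythroid 0.137. Median centring gave mTORC1 0.0841, ribosomal 4.77e-04, cholinergic 0.0502, erythroid 0.227 and a turned adrenal cortex list at 0.926. Cy3 alone gave immediate early 0.0588 and ribosomal 0.0128. Requiring signal in Cy3 on all arrays gave cholinergic 0.890, mesenchymal 0.0545, Schwann 0.274 and muscle 0.0878; requiring both channels gave cholinergic and mesenchymal 0.0618, Schwann 0.0679, erythroid 0.128 and muscle 0.0547. Slide as a fixed block gave mTORC1 0.0677 and a turned adrenal cortex list at 0.867, and as a random block immediate early 0.0900. The replicate block changed no list call but ended those of the genes Marco (0.0758), Osmr (0.0575) and Th (0.0596). Fry gave immediate early and mesenchymal 0.135, FOXO 0.0491, ribosomal 0.0173, fibroblast 0.154, interferon 0.142, adipocyte 0.0750 and muscle 0.0970. The exact permutation gave immediate early 0.0952, mTORC1 0.138, mesenchymal 0.152, fibroblast 0.178, endothelial and macrophage 0.0516, interferon 0.138 and adipocyte 0.103. Without the 3 tumours immediate early reached 0.221, Schwann 0.133, erythroid 0.0590 and a turned adrenal cortex list 0.0658. With the stromal covariate FOXO reached 0.00635, p53 0.0204 and adipocyte 0.371, and the JAK/STAT (0.523), mesenchymal (0.543), fibroblast (0.0510), T and NK (0.391) and interferon (0.188) lists turned. Leaving out each tumour gave ranges of 0.00231 to 0.160 for immediate early, 0.0123 to 0.0614 for mTORC1, 0.0417 to 0.154 for ribosomal and 0.0583 to 0.727 for adrenal cortex, the last turned without ALK/MYCN 3.

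Alk turned to -0.13 in the scanner-processed signals and the deposited values, to -0.20 after scaling, and ranged from -0.059 to 0.27 on leaving out each tumour. Th turned to -0.019 with median centring and -0.040 with scaling, Ddx1 to 0.068 with spike-in centring, and Star to -0.058 without the 3 tumours and, on leaving out each tumour, ranged from -0.053 (without ALK/MYCN 3) to 1.81. Mycn ranged from 2.55 to 3.04 on leaving out each tumour. Of 74 named genes that passed, 58 passed with the stromal covariate, the others being Acta2, BRN1-A, C1qb, Cd79b, Cldn5, Fabp4, Fbln2, Igh-VJ558, Ly6c1, Marco, Meis2, Nr4a1, Nts, Osmr, Th and Tyrobp. Differences moved by over 1.5 times in 20 of the 74 with Cy3 alone, 17 with the stromal covariate, 12 in the scanner-processed signals, 8 with spike-in centring and 7 with the mean over probes. Those 7 were Asb4, Csf1r, Igh-VJ558, Mybl2, Pcdhac2, Pgm5 and Wdfy1.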

Other observations

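All tests in this part were chosen after the differences of single genes and lists had been seen, and the genes named were chosen after their values were seen; several families share members with lists of the report, cholesterol synthesis with the sterol list, replication with the cell cycle list, and contactins with the neuronal list. Of 20 measured genes of cholesterol synthesis 17 rose and none fell, with a median difference of 0.94, including Tm7sf2, a sterol reductase gene, at 1.10 ± 0.12 (SE, limma adjusted p = 5.24e-04, n = 5 per group). Subunits of the V-ATPase, the proton pump of lysosomes and synaptic vesicles, rose in 16 of 21 cases with none lower, with Atp6v0a1 at 1.36 ± 0.12 and Atp6v0e2 at 1.08 ± 0.11. Clustered protocadherins, adhesion proteins of neurons, rose in 13 of 27 cases with none lower (8 with the stromal covariate, 20 with spike-in centring). Among them were Pcdhac2 at 1.57 ± 0.19 and Pcdhb10 at 0.59 ± 0.10. Contactins and neurexins rose in 6 of 7. Genes of DNA replication were lower in 17 of 34 cases with none higher (6 lower and 4 higher with spike-in centring), with Gins2 falling by 0.81 ± 0.07, and mitochondrial ribosomal proteins in 23 of 77 with 1 higher, a direction that turned with spike-in centring, where 16 were higher and the median moved from -0.16 to 0.094. Chemokines and their receptors were lower in 8 of 32 cases with none higher, with Cxcl16 falling by 1.10 ± 0.18. The medians of the other 6 families kept their sign under each scaling, that of replication reaching -0.091 with spike-in centring, and 2 chemokine genes were lower with the stromal covariate.

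These were the clearest of 37 families tested. With the preset correlation 16 families passed camera, among them cholesterol synthesis (limma adjusted p = 1.21e-09), replication (1.54e-08), V-ATPase (1.88e-07), contactins and neurexins (1.50e-05), protocadherins and mitochondrial ribosomal proteins (2.00e-05 each) and chemokines (3.05e-04). The hypothesis that family members shift together beyond other genes could not be upheld with an estimated correlation, under which 0 of the 37 passed. The lowest such adjusted p was 0.105, for contactins and neurexins, and it was 0.439 for cholesterol synthesis. The exact permutation of tumour means gave an adjusted p of 0.0245 for each of these families but the chemokines, at 0.0420. Proteasome subunits and kinesins reached the same 0.0245, with medians of -0.013 and 0.0056. Neither passed camera (adjusted p = 0.523 and 0.525), so this value does not set the named families apart.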
